A study of Homo sapiens with 2 samples.

How the data were processed

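RNA of 2 SW480 lines was measured on 2 membrane oligonucleotide arrays for the human Wnt signalling pathway. SW480 is a human colorectal adenocarcinoma cell line. One line carried a vector with green fluorescent protein (GFP) only, and the other overexpressed hiNOS, an inducible nitric oxide synthase (iNOS), together with GFP. Per the labels' protocols, both were sorted on GFP and cultured further as stable lines, and total RNA was converted to biotin-labelled cRNA. Each group holds 1 array. The series text speaks of several RNA preparations assayed more than once, and arrays other than these 2 were not analysed here.

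Per the series text, arrays were imaged by autoradiography and the scans were read with GEArray Expression Analysis Suite 2.0. The deposited intensity is the average density of each of 128 spots in scanner units, with the Clover setting off per the file headers, no background removed and no normalization. A further deposited intensity table was found to be density less the mean of the 2 blank spots, divided by the mean of the middle 50% of all 128 spots after the same subtraction. This rule gave every deposited value to within 0.005, so its scale is linear, it is not centred and its direction is settled. The medians of its columns were 0.54 for GFP and 0.50 for hiNOS. The authors' deposited table of genes beyond 2-fold holds hiNOS over GFP on that scale, with blank positions 116 and 117 as background per the file headers. These deposited values were treated as a score, not a plain ratio, because spots with a density under that of the blanks give negative values. One more deposited table of intensity subtracts the lowest spot and divides by positions 122 to 126, but it averages the 2 arrays and so holds no comparison. The series text names GAPDH and ACTB as the reference for normalization, whereas these headers name other references.

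The authors' software called a spot absent when its density was under 1.5 times the mean local background of the lower 75 percentile of spots that do not bleed, per the file headers. A spot was called bleeding when it was brighter than the mean of all spots and within 30% of its own local background. These calls were used as deposited.

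Density was divided by the mean of the 3 GAPDH and ACTB spots of the same array, as the series text describes, and the log2 ratio of hiNOS over GFP was taken. No further background subtraction was part of this setting, which was fixed before the data were examined on the premise that densities had already been corrected. They had not, and with blanks averaging 12750 units (GFP) and 12336 (hiNOS) a ratio of densities understates a change. The setting was kept, and the ratio after blank subtraction, on the scale of the deposited values, is printed beside it where a fold is given. On simulated arrays of 113 genes with the measured blanks and a true log2 change of 1.5 up or down in 30 genes, the raised genes had a median of 1.51 after blank subtraction and 0.67 from density alone. The blanks were added to each simulated signal and then removed, so the recovery follows from the construction. The simulation held no genes at background and imposed no ceiling, so it shows only how the blanks compress a ratio for genes above background.

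Of the 128 spots, 113 were pathway genes, 7 were spots of 5 housekeeping genes, 6 were blanks, plasmid or artificial-sequence spots taken here as negative controls, and 2 were a biotinylated positive control. RefSeq accessions in the files named 112 of the 113 genes in the current human annotation. The symbol printed on the array was kept, except that position 51, given as C2orf31, is named FZD5 after its accession and description. Other symbols that have since changed are AES (now TLE5), SHFM3 (FBXW4), SLC9A3R1 (NHERF1), T (TBXT), WISP1 (CCN4), WISP2 (CCN5) and HSPCB (HSP90AB1). Probe sequences and coordinates were not used here, and related genes could cross-hybridise.

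With 1 array per group no test was possible, so no p-value compares the groups. Genes above background on at least 1 array were counted by a fixed rule of 2-fold. A gene absent on 1 array received a lower bound: its bright value over the higher of its own dim value and the dimmest present gene of the dim array. Size was set against the spread of the log2 ratio over the 6 negative-control spots and against its range over the genes absent on both arrays, neither of which is replicate error, with genes absent on 1 array taken at their bounds (at 1-fold where no bound was above 1). The use of the range was chosen after the data were seen. Spots at 90% or more of the positive control's mean are called near the ceiling, also a choice made after the data were seen. The name gives their place in the range only, and whether the film or scanner saturated there was not settled.

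Of 11 pathway lists fixed beforehand, those with at least 3 members above background were described by the median log2 ratio and its percentile among 10000 random lists of the same size matched on density in 3 classes. On the same simulated arrays the list method placed a raised list at percentile 99.97 and put 6.0% of 200 random lists outside the central 95%. How it behaves where spots crowd near a ceiling was not simulated. Genes named are the 10 highest and the 10 lowest ratios among genes above background, a preset group (NOS2, DKK1, CTNNB1, MYC, CCND1, AXIN2, LEF1, TCF7, TCF7L2, MMP7, GAPDH, ACTB) and up to 4 members of each list, the 2 highest and the 2 lowest. NOS2 and MMP7 were not among the genes of the array. Where another gene is named, it was chosen after its values were seen.

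Alternatives were GAPDH alone, ACTB alone, all housekeeping spots, the median gene, quantile normalization, normexp with an offset of 50, subtraction of the median negative control, other filters on dim spots, the deposited values and a rule of 1.5-fold. Subtraction of the blanks with GAPDH and ACTB scaling, background set by the highest negative control, and leaving out genes near the ceiling on either array were added after the data were seen. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1. The precision of every value is limited by the number of arrays.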

Results

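Expression of 113 genes in and downstream of the Wnt pathway was measured in SW480 cells that overexpressed inducible nitric oxide synthase (hiNOS) and in SW480 cells with the GFP vector alone, on 1 array each. The comparison asks how Wnt pathway transcripts differ when the enzyme is overexpressed. NOS2, which encodes the enzyme, was not on the array, so the overexpression itself could not be checked here. No value below has a replicate, and each difference describes these 2 arrays.

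The arrays were alike in range. Density ran from 10394 to 50465 units on the GFP array and from 10508 to 49808 on the hiNOS array, with medians of 17394 and 16791. The 6 negative-control spots averaged 12354 ± 328 (SD over spots) on the GFP array and 12187 ± 740 on the hiNOS array. Present calls covered 53 genes with GFP and 51 with hiNOS. Of the 113 genes, 45 were present on both arrays, 8 on the GFP array alone, 6 on the hiNOS array alone and 54 on neither. At the bright end, 19 genes lay near the ceiling on both arrays, and their log2 ratios ran only from -0.05 to 0.06. The 7 housekeeping spots lay there as well, between 47374 and 50151 units, and 6 of them were called bleeding on each array. Whether such spots could register a difference was not settled.

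Between the extremes, the highest ratios of density on the hiNOS array belonged to CTNNBIP1, which encodes an inhibitor of the binding of beta-catenin to TCF factors, to NKD1 and NKD2, which encode Dishevelled-binding antagonists of the pathway, and to the casein kinase gene CSNK1D. The lowest ratios of density belonged to APC2, a homolog of the tumour suppressor APC, to the Groucho-type corepressor TLE4, to the ligand WNT5A and to CSNK1A1, whose kinase primes beta-catenin for degradation. After blank subtraction the order differed, and genes absent on 1 array, whose folds are only bounded, took most of the outer places: the measured fold was 3.31 for CSNK1A1L and 2.43 for CTNNB1 on the higher side, and 4.50 for DAAM2 and 3.83 for TLE1 on the lower side. CTNNBIP1 had a density of 15149 with GFP, where it was called absent, and 29055 with hiNOS. That is at least 1.54-fold higher by density and at least 2.83-fold higher once the blanks were subtracted. APC2, present on both arrays, had 37643 units with GFP and 19254 with hiNOS, which is 1.95-fold lower by density and 3.41-fold lower after blank subtraction.

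By the preset rule, density over GAPDH and ACTB, 0 genes were 2-fold higher and 0 were 2-fold lower on the hiNOS array. After subtraction of the blanks, on the scale of the deposited values, 6 genes were 2-fold higher and 10 were 2-fold lower among the 59 present on at least 1 array. Of these 16 genes 12 were absent on 1 array, so that their folds are only bounded. With those genes at their bounds, 3 were 2-fold higher (CSNK1D, NKD1 and CTNNBIP1) and 4 were 2-fold lower (APC2, CSNK1A1, TLE4 and CSNK2A2), and of these CSNK1D, NKD1, APC2 and CSNK1A1 were present on both arrays. Over the 54 genes absent on both arrays the log2 ratio of density had an SD of 0.12 and ran from -0.41 to 0.36. Over the 6 negative controls the SD was 0.08 and the range -0.11 to 0.11. The ends of the wider range were FRAT2, at 16726 units with GFP, and NLK, at 17005 with hiNOS. Both were brighter there than every negative control, so that range may hold differences in signal. A gene inside it is therefore not shown to be unchanged. With genes absent on 1 array at their bounds, 4 higher genes (CTNNBIP1, CSNK1D, NKD1 and NKD2) and 6 lower genes (APC2, TLE4, WNT5A, CSNK1A1, CSNK2A2 and WNT3) lay beyond the range of the absent genes. The measured ratios of CSNK1A1L, CTNNB1, DAAM2, FRZB, MYC, PPP2CA and TLE1 lay beyond it too, but their bounds did not.

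**Figure D1:**
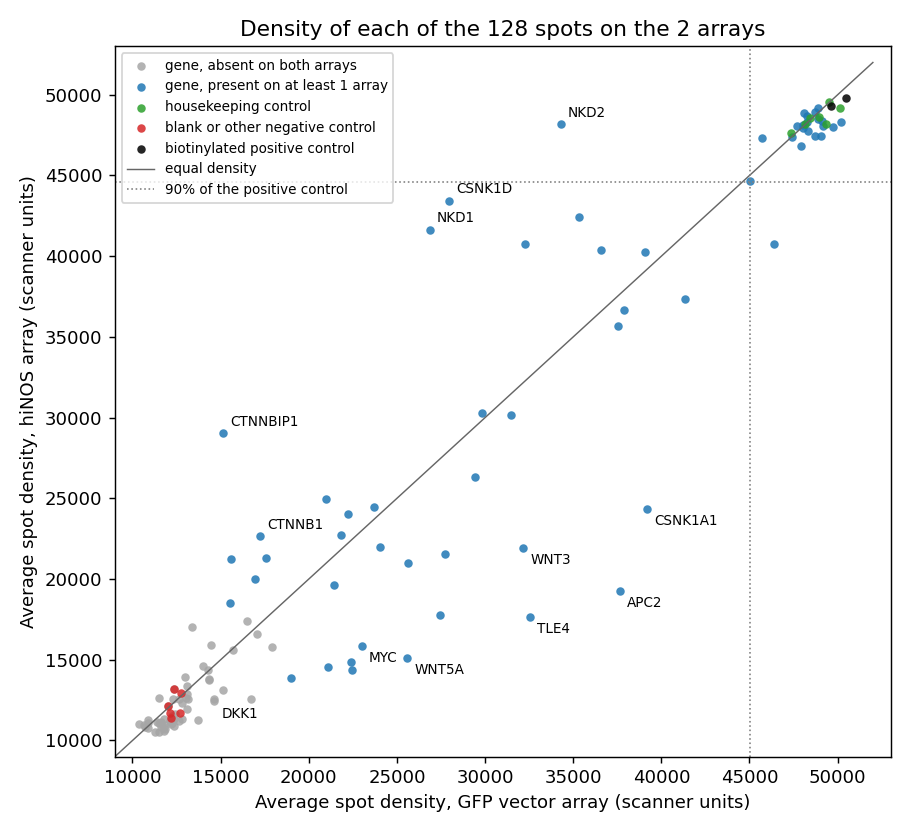
Average spot density in scanner units on the GFP vector array (x axis) and the hiNOS array (y axis), 1 point per spot, coloured by kind of spot, with the line of equal density and dotted lines at 90% of the biotinylated positive control. The 54 genes absent on both arrays sit at low density, among the negative controls, below them down to 10394 units (FZD4 with GFP) and above them up to 17897 units (WNT2B with GFP). Near the ceiling on both arrays 19 genes crowd with the housekeeping spots, and CTNNBIP1 and APC2 lie far from the line on either side.

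Among the nuclear corepressors and inhibitors of TCF, 4 of 10 genes on the array were above background. CTNNBIP1 was higher with hiNOS, while TLE4, a Groucho-type corepressor, was lower. TLE4 went from 32539 to 17654 units, at least 1.75-fold lower by density and at least 3.03-fold lower after blank subtraction. TLE1, of the same family, went from 18982, the dimmest present gene of the GFP array, to 13878, which bounds the density ratio only at 1.02-fold and leaves no bound above 1 after subtraction. AES, a shorter member of the same family, lay near the ceiling on both arrays. The median log2 ratio of the list was -0.22, at percentile 22.3 of matched random lists. With the 3 genes absent on 1 array at their bounds it was -0.01, and with background set by the highest negative control it was 0.01 at percentile 73.3. Under the settings that remove background it ran from -0.65 at percentile 12.3 with normexp to -0.94 at percentile 9.2 with the blanks subtracted, from measured ratios of genes absent on 1 array. No direction is given for this list, because its value rests on 3 genes absent on 1 array. The other 8 lists with a percentile had medians close to 0, and another scaling turned their sign, by a shift of all genes alike or, for the casein kinases, by quantile normalization (0.01). No direction is given for them either.

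Dishevelled and its cytoplasmic partners had 6 of 13 genes above background. NKD1 was 1.56-fold higher by density, from 26856 to 41641 units, and 2.19-fold higher after blank subtraction. NKD2 went from 34302 to 48173 units, which is near the ceiling, and was 1.41-fold and 1.75-fold higher on the same scales, which a ceiling would make lower bounds. DAAM2, a formin gene of the planar polarity branch, went from 22445 to 14378 units and was at least 1.21-fold lower by density and at least 1.49-fold lower after subtraction. DIXDC1 had a log2 ratio of -0.15, inside the range of the absent genes, and DVL1 and DVL3 were near the ceiling on both arrays. The median of the 6 was 0.01, at percentile 66.4, a value set by DVL1 and DVL3. Leaving out genes near the ceiling on either array also dropped NKD2, which was higher. The 3 genes left had a median of -0.15, at percentile 30.6, which is the ratio of DIXDC1.

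For the casein kinases, 7 of 8 genes were above background and members differed in both directions. CSNK1D was 1.56-fold higher by density and 2.16-fold higher after subtraction, at 27934 units with GFP and 43447 with hiNOS. CSNK1A1 was 1.60-fold lower and 2.09-fold lower on the 2 scales, from 39171 to 24344 units. CSNK2A2 went from 27442 to 17769 units, at least 1.47-fold lower by density and at least 2.25-fold lower after subtraction. CSNK1G1, absent with GFP, went from 15520 to 18525 units, which allows no bound above 1 by density and at least 1.05-fold higher after subtraction. CSNK1A1L, a close homolog of CSNK1A1 outside the list, differed in the opposite direction, from 15584 to 21231 units, at least 1.12-fold higher by density and at least 1.5-fold higher after subtraction, and was absent with GFP. Probe sequences were not used here, so the values of this pair of near-identical genes are uncertain. For the 7 casein kinases the median was -0.12, at percentile 25.1, and without spots near the ceiling it was -0.20, at percentile 27.5.

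The beta-catenin destruction complex and its ubiquitin ligase had 6 of 9 genes above background. APC2 and CSNK1A1 were lower with hiNOS. AXIN1, at 23687 and 24444 units, had a log2 ratio of 0.05, and the F-box gene FBXW11 one of 0.03. AXIN2 and GSK3A lay near the ceiling on both arrays. APC, GSK3B and BTRC were absent on both. The complex had a median of -0.00, at percentile 58.9, a value set by AXIN2 and GSK3A. Without spots near the ceiling it was -0.33, at percentile 7.72. Of the PP2A subunits, PPP2CA, a catalytic subunit, went from 21117 to 14570 units, at least 1.13-fold lower by density and at least 1.28-fold lower after subtraction, and PPP2R1A was near the ceiling on both arrays.

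TCF/LEF factors and nuclear coactivators had 5 of 9 genes above background. CTNNB1, which encodes beta-catenin, was absent with GFP at 17226 units and present with hiNOS at 22673, at least 1.20-fold higher by density and at least 1.75-fold higher after subtraction. The transcription factor genes TCF7, TCF7L2 and TCF7L1 had log2 ratios of 0.07, 0.05 and -0.07, within 1 SD of the negative controls. Those controls are dimmer spots, so their SD does not give the scatter at the density of these genes. After blank subtraction TCF7 was 1.21-fold and TCF7L2 1.12-fold higher, and TCF7L1 was 1.01-fold lower. LEF1 was absent on both arrays, at 12821 and 12322 units. These 5 genes had a median of 0.06, at percentile 84.7, the ratio of a gene near the ceiling. Without it the median was 0.06, at percentile 65.3.

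Wnt target genes had 9 of 16 members above background, and 4 of these (AXIN2, CCND1, CCND3 and FOSL1) were near the ceiling on both arrays. MYC, absent with hiNOS, went from 23002 to 15870 units, at least 1.24-fold lower by density, which is inside the range of the absent genes, and at least 1.57-fold lower after subtraction. NKD1 was higher, as given for the partners of Dishevelled. CCND2, a cyclin D gene absent with GFP, went from 17562 to 21317 units and was at least 1.13-fold higher by density and at least 1.52-fold higher after subtraction. JUN, near the ceiling with GFP, went from 46381 to 40784 units and was 1.13-fold lower by density and 1.12-fold lower after subtraction, which a ceiling would make lower bounds. CCND1 had 49108 and 48373 units and AXIN2 had 47923 and 46845. Over the 9 targets the median was -0.02, at percentile 34.8, which is the ratio of CCND1. Leaving out genes near the ceiling on either array also dropped JUN, and the 4 targets left had a median of 0.18, at percentile 85.4.

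Wnt ligands had 11 of 19 genes above background, 6 of them near the ceiling on both arrays. WNT5A, a ligand of the branches that do not act through beta-catenin, went from 25564 to 15127 units and was at least 1.37-fold lower by density and at least 1.96-fold lower after subtraction. WNT3 was present on both arrays and went from 32175 to 21952 units, 1.46-fold lower by density and 1.92-fold lower after subtraction. WNT7B had a log2 ratio of 0.12, and WNT8A was near the ceiling on both arrays. Their median was -0.04, at percentile 1.7, the 1 list of 9 tested outside the central 95%. That median is the ratio of WNT5B, a spot near the ceiling on both arrays. Without genes near the ceiling on either array 4 ligands were left, with a median of -0.33, at percentile 25.0, and 0 lists lay outside. With the deposited scaling the median of the 11 was 0.03.

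Of the Frizzled and LRP receptors, 4 of 12 genes were above background, and FZD2, FZD1 and FZD9, present on both arrays, lay inside the range of the absent genes. FZD2 had 32261 and 40749 units with a log2 ratio of 0.34 (1.54-fold after subtraction), FZD10, absent with GFP, was at least 1.06-fold higher by density and at least 1.30-fold after subtraction, FZD1 had -0.05 and FZD9 had -0.14. The receptors had a median of 0.10, at percentile 73.8, and of 0.01 with FZD10 at its bound. Over genes present on both arrays it was -0.05, at percentile 22.6, with background set by the highest negative control -0.05, at percentile 34.9, and on the deposited values 0.31. RHOU, the only gene on the array from the list of small GTPases and kinases of the non-canonical branches, was absent on both arrays.

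The extracellular Wnt inhibitors had 6 of 11 genes above background. FRZB, a secreted Frizzled-related antagonist, went from 22395 to 14870 units and was at least 1.20-fold lower by density and at least 1.48-fold lower after subtraction. DKK4 was 1.28-fold lower by density and 1.54-fold lower after subtraction, with 27749 and 21559 units and a log2 ratio of -0.36, inside the range of the absent genes. KREMEN2, a receptor for Dickkopf proteins, had 35352 and 42434 units with a log2 ratio of 0.27 (1.40-fold after subtraction), and SFRP4 had 0.15. Among these 6 inhibitors the median was -0.03, at percentile 51.6, and without spots near the ceiling -0.04, at percentile 47.3. DKK1, a secreted antagonist of the LRP co-receptors, was called absent on both arrays, so no fold is given from the densities. It had 14628 units with GFP, above the brightest negative control of that array at 12779, and 12422 with hiNOS, where the brightest negative control had 13214. The authors' deposited table lists DKK1 at a ratio of 0.048, from 1878 units above the blanks with GFP and 85.7 with hiNOS.

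**Figure D2:**
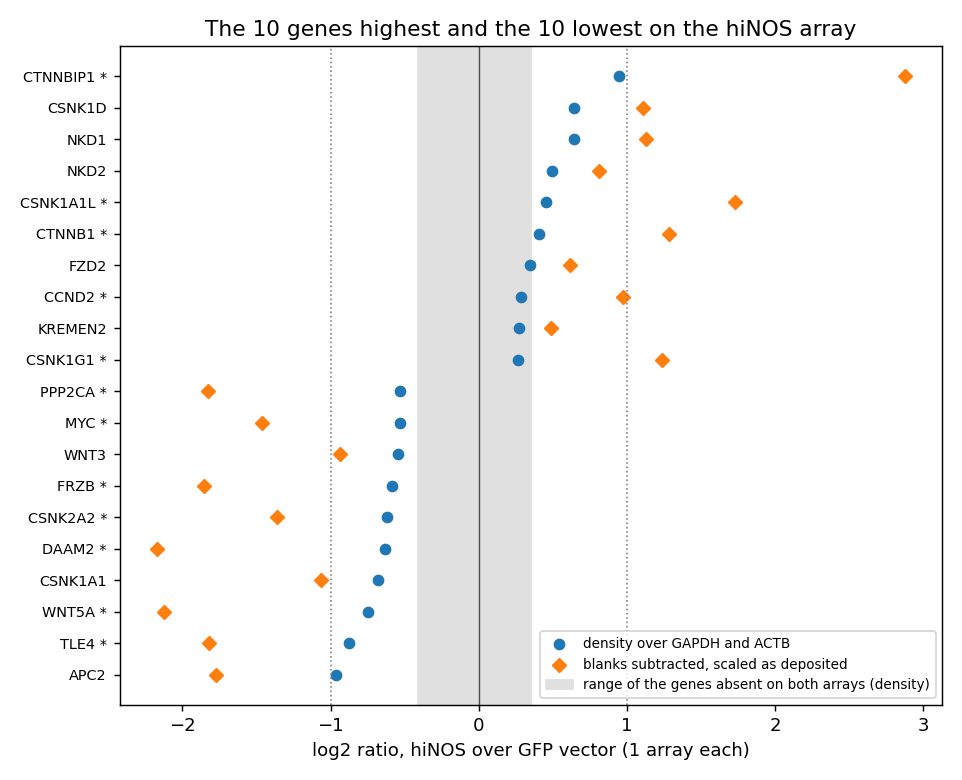
Log2 ratio of hiNOS over GFP vector (x axis, 1 array each) for the 10 highest and the 10 lowest genes above background (y axis), from density over GAPDH and ACTB (circles) and after blank subtraction on the deposited scale (diamonds), with dotted lines at 2-fold. The grey band marks the range from -0.41 to 0.36 of the density ratios of genes absent on both arrays. It applies to the circles, for which it may hold differences in signal besides scatter, and is no measure of scatter for the diamonds. An asterisk marks a gene absent on 1 array, whose measured ratio is plotted and whose bound is smaller, and no circle reaches 2-fold, whereas 6 diamonds on the right and 9 on the left do.

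The authors' deposited table lists 16 genes as over-expressed and 23 as under-expressed with hiNOS, besides 2 artificial-sequence control spots. Its positive ratios were recomputed from density with a largest difference of 3.55e-15. Of the 39 genes, 16 were present on at least 1 array, 6 over and 10 under, and for all 16 the density differed in the listed direction. That direction was largely fixed in advance, because the listed ratios come from these same densities and all 16 lay above the blank means. The other 23 were absent on both arrays, 10 over and 13 under, and 8 of the 39 listed ratios were below 0.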

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

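Subtraction of the blanks, the highest negative control and the ceiling spots left out were settings chosen after the data were seen. Counts of 2-fold genes differed most with the treatment of background. The density ratio gave 0 higher and 0 lower, as it did with GAPDH alone, ACTB alone, all housekeeping spots, both filters on dim spots, background set by the highest negative control, and without spots near the ceiling. Counts differed with the median gene (0 higher, 1 lower), quantile normalization (1 higher, 0 lower), normexp (2 higher, 10 lower), the median negative control subtracted (6 higher, 10 lower), the deposited values (6 higher, 10 lower), the blanks subtracted with GAPDH and ACTB scaling (6 higher, 11 lower) and a 1.5-fold rule (3 higher, 6 lower). A constant background under both arrays pulls a ratio towards 1 by construction. The median gene moved the median log2 ratio of genes above background by -0.12 and the other settings by less than 0.1. The Wnt ligands were the 1 list outside the central 95%, and 0 lists were with quantile normalization, no filter, genes present on both arrays, the highest negative control or the ceiling spots left out, where the cause was not tested. No paired analysis was possible because each group has 1 array, which also rules out leaving out a replicate. Signal over background limits the 54 genes absent on both arrays, and a ceiling, if there is one, limits the 19 genes near the positive control on both.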

Other observations

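Of the tests in this section, the share of listed genes above the blank mean, the comparison of listed directions with density, the rank of DKK1 and, for neighbouring genes, the intervals, the test of the difference and the values without 2 pairs were chosen only after the results were seen. Outside the fixed lists, FOXN1, which encodes a forkhead transcription factor, was present on both arrays at 20960 and 24972 units, 1.20-fold higher with hiNOS by density, 1.62-fold higher after blank subtraction, and by density inside the range of the absent genes. SLC9A3R1, which encodes a scaffold protein of the apical membrane, lay near the ceiling on both arrays, at 49194 and 48038 units. FSHB, MARK4, FBXW2 and SHFM3 were absent on both. These genes were chosen because no list held them.

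Folds are listed in the deposited table for 23 genes that were absent on both arrays. On at least 1 array 15 of them lay below the blank mean, as 0 of the 16 listed genes present on at least 1 array did, so their listed values hold a term below 0 and are no folds of a signal. For the other 8, subtraction of the blank spots stays open as the cause: with either blank alone as background (11708 and 12964 units on the hiNOS array) 37.5% (3 of 8: BCL9, NLK and PPP2R1B, exact 95% interval 8.52 to 75.5%) stayed beyond 2-fold in the listed direction. To stay, a gene also had to lie above that blank on both arrays. Density differed in the listed direction for 56.5% (13 of 23). The 10 that differed the opposite way each lay below the blank mean on at least 1 array. DAAM1, listed at 10.0-fold over-expressed, had 12629 units with GFP and 11180 with hiNOS, both below the blank means. The 8 genes above the blank means on both arrays all differed in the listed direction, which that place largely fixed in advance. The share therefore cannot weigh a difference in density as the cause. DKK1 stays open, because 3 of the 54 genes absent on both arrays (5.56%, exact 95% interval 1.16 to 15.4%), DKK1 included, had a log2 ratio as low as its -0.23. Its listed decrease held with the blank that had the lower density on the hiNOS array. With the other blank, at 12964 units, the 12422 units of DKK1 with hiNOS lay below the background, so no ratio could be formed.

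Genes crowded at the top of the density range. On the GFP array 20 genes lay at 90% or more of the positive control and 2 at 80% to 90%, and on the hiNOS array 21 and 7, so the smaller of the 2 ratios was 3. These counts restate the crowding and do not separate a ceiling of the film or scanner from many bright transcripts, and both stay open. No gene exceeded the brightest control spot on its array. If there is a ceiling, the GAPDH and ACTB spots used for scaling could not register a difference in input.

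Genes at consecutive positions often differed in the same direction, such as CTNNB1 with CTNNBIP1 and NKD1 with NKD2. Over 112 adjacent pairs the log2 ratios of density had a Pearson r of 0.184 (1-sided permutation p = 0.0185, 0.0278 after Benjamini-Hochberg adjustment over 3 correlations) and a Spearman rho of 0.20, across genes of 1 pair of arrays, which are not independent replicates. The rows and columns of the membrane were not used here, so adjacency means consecutive position numbers, which need not be physical neighbours. Symbols run in alphabetical order, so families sit side by side. Pairs that share the first 3 letters were taken as 1 family, a rule that also joins CTNNB1 to CTNNBIP1, which encodes an inhibitor of beta-catenin. For these 65 pairs r was 0.339, and it was 0.218 without the CTNNB1 and NKD1 pairs. For the other 47 pairs r was -0.0374 (95% interval -0.321 to 0.252), with a 2-sided permutation p of 0.0836 for the difference. A local effect on the membrane and a shared change or cross-hybridisation within families may each contribute and cannot be told apart here, because the interval of the 47 pairs reaches the r of all pairs and the layout is open.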
